A study of Mus musculus with 14 samples.

How the data were processed

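Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 7 cell types sorted by antibody staining from adult C57BL/6 mice, with 2 libraries per cell type and 14 libraries in all. Per the labels, MPP, CMP, CLP, GMP, MEP and ProB cells came from bone marrow and ProT cells from thymus. The labels do not say whether the 2 libraries of a cell type came from different animals.

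The values used here are the deposited annotated master list of 92842 peaks of all cell types together. Per the file header, the authors annotated the list with the annotatePeaks program against mm10, and the submitters' processing notes name HOMER 4.10.2 and the mm10 build. The aligner, the peak caller, its threshold and the way in which the peaks of single libraries were merged are not given in the sources used here. For each peak the deposited list gives its position, its annotation class, the element it lies in, its nearest TSS and the signed distance to it in bp. The peak score in the deposited list is 0 for every peak and was not used. No values per library or per cell type were analysed here, so depth is unknown, an SD below is a spread over genes, and the 9 comparisons between cell types planned before the data were examined were not made. In a merged list a peak may have been open in any of the cell types, and the list weights the cell types in a way that cannot be seen from it. Peaks of a fixed width of 499 bp hold no information on the width of the open region, and a peak was given to the gene with the nearest TSS, which need not be the gene it regulates.

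Gene identifiers of the list were matched to a RefSeq gene table of assembly GRCm38.p6, whose primary assembly is that of mm10. Of the 19105 genes named as nearest, 19068 (99.8%) were matched. In all, 435 peaks were left out of the counts per gene, 304 of them because the table puts their gene on another chromosome. The position and strand of each TSS were recovered from the peak centres and the distances in the list, using the fact that no TSS can lie closer to a peak than the distance given. A gene's territory was the stretch nearer to its TSSs than to any other TSS. Of the genes without a peak, 5941 could be placed and 1282 could not. Those 1282 have no territory and were left out of all counts of genes, so shares of coding genes with a peak are somewhat too high. The territory map was revised after a first set of list tests had been seen. In the first map the strand came from the closest gene end and genes without a peak sat at their midpoint, and it returned the listed distance for 87.2% of the peaks, against 100.0% for the revised map. That gain largely follows from its construction, since each TSS is set at a listed distance and places contradicting the distances are excluded. The agreement is therefore no test of the revised map. Results under the first map are given as an alternative.

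Fixed before the data were examined were 14 gene lists (222 entries, 217 different genes): 7 of blood lineages, 5 of other cell types that a sort could hold, 1 of housekeeping genes and 1 of genes of unrelated tissues. For each list, the mean number of peaks per gene with at least 1 peak was compared with 100000 random lists of the same size, drawn from all genes with a peak in the same 10 bins of territory size (two-sided permutation test). The share of a list's peaks within 1 kb of a TSS was compared with that of all other peaks, and the share of its coding genes with such a peak with that of all other coding genes, by Fisher's exact test (two-sided). Each family of 14 tests was adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The share of genes with a promoter peak was added after the data had been seen. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Genes were named by a rule fixed in advance: in each list the 3 genes with the most peaks and every member without a peak, and among all genes the 15 with the most peaks and the 10 with the most peaks per 100 kb among those with at least 5. Genes that tie for the third place all count, not every gene that the rule picks is named in the text, and the peak nearest to the TSS was taken as the region of a named gene. The genes of the enhancers were listed before their peaks were examined, from memory and without a source being consulted. Other genes named outside the rule, such as those at receptor loci, were chosen after their values had been seen.

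The list test was tested on simulated data made from the real genes. Of 200 random lists of 18 genes, it called 4% with no effect, without adjustment. It called 36.5% when each count was replaced by a Poisson draw with 1.5 times the count as its mean, and 89% at 2 times. These runs drew fewer random lists per test than the tests on the real lists. Fisher's exact test over peaks called 4.5% of 200 random lists. Alternatives set in advance were peaks within 50 kb or 10 kb of a TSS, no matching on territory, genes with 0 peaks kept, genes of more than 1 list left out, promoter limits of 500 bp and 2 kb, peaks over 100 kb away left out, and a random subset of the peaks. Added after the data had been seen were the list without its member with the most peaks, the median, genes in place of peaks as the unit, other limits for the promoter share of genes, and the first territory map. The 18 planned motif searches need a genome sequence and were not run. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.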

Results

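Open chromatin was mapped in 7 populations of the mouse blood system: multipotent progenitors (MPP), common myeloid (CMP) and common lymphoid (CLP) progenitors, granulocyte-macrophage (GMP) and megakaryocyte-erythroid (MEP) progenitors, pro-B cells (ProB) and pro-T cells (ProT). Each was sorted for 2 libraries. The merged list of all 14 libraries held 92842 peaks of 499 bp, which did not overlap and covered 46.3 Mb, with a median gap of 8258 bp between neighbours. The values carry no cell type, so the comparisons below set groups of genes, not groups of libraries, against each other, and there are no replicates.

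The first question was where in the genome the peaks lay. Introns held 42.0% of the peaks and intergenic sequence 39.3%. Promoter-TSS sites held 11.6%, with peaks from -1000 to 954 bp around a TSS. These are observed distances, not limits of the class: the Ikzf1 peak 105 bp downstream of its TSS counts as 5' UTR. Exons outside the UTRs held 2.67%, transcription termination sites 1.61%, 5' UTRs 1.30%, 3' UTRs 1.09% and non-coding genes 0.427%. In all, 15007 peaks (16.2%, exact 95% interval 15.9 to 16.4) lay within 1 kb of a TSS, while 37.1% lay 10 to 50 kb away, and the median distance was 18164 bp. More peaks lay over 1 kb downstream of the nearest TSS (48.7%) than over 1 kb upstream (35.1%).

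**Figure D1:**
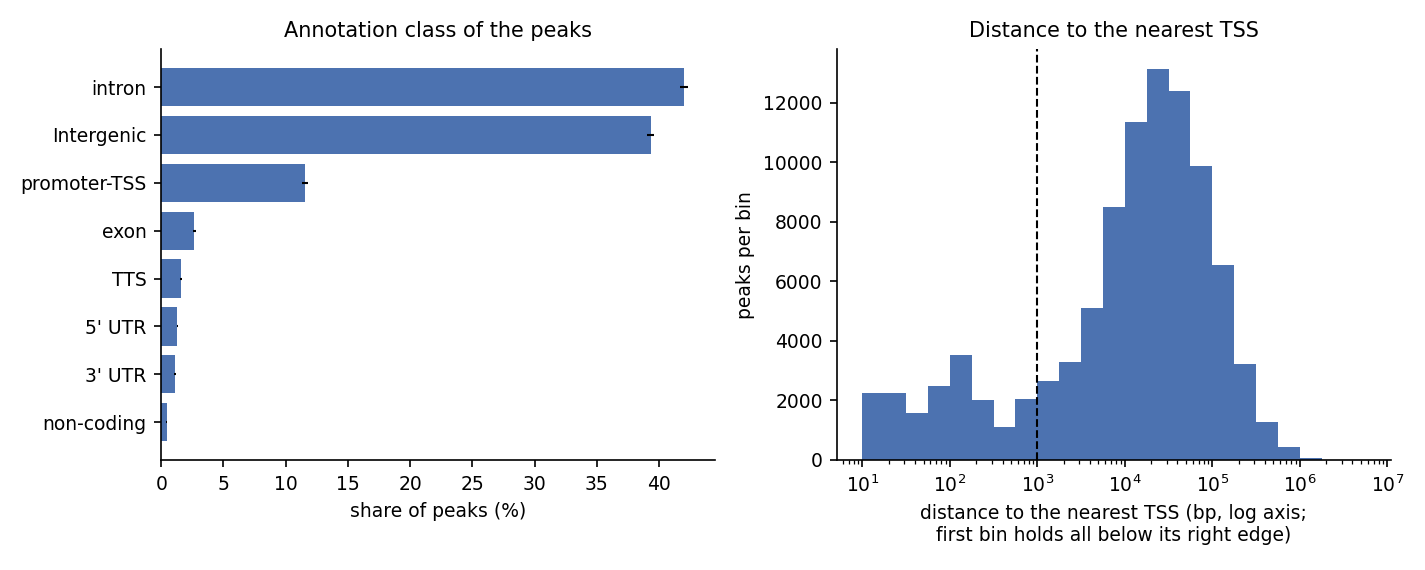
Share of the 92842 peaks in each annotation class in percent, with exact 95% intervals as error bars (left), and number of peaks by distance to the nearest TSS in bp on a log axis (right). The dashed line marks 1 kb, and the larger of the 2 groups of peaks lies beyond it, where 83.8% of the peaks are found.

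The autosomes held 28.2 to 49.0 peaks per Mb (mean 37.6 ± 5.26, SD, n = 19 chromosomes), with the lowest value on chromosome 14 and the highest on chromosome 11. The X chromosome held 11.3 peaks per Mb. The gap was smaller at promoters: 45.2% of the coding genes of the X with a territory had a peak within 1 kb of a TSS, against 46.9% to 67.0% on the autosomes. These differences between chromosomes were not tested.

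Peak number per gene varied widely. Foxp1, a forkhead transcription factor needed in B cell development, had 88 peaks in a territory of 866 kb that reaches beyond the gene (chromosome 6, 98925342 to 99522746). Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, had 57, Elmo1, a regulator of Rac signalling and cell migration, had 56, and Btg1, an antiproliferative gene, and Cxcr4, the receptor that holds progenitors in the bone marrow, had 47 each. Also among the 15 genes with the most peaks were Zfp608 with 63, Tbl1xr1, a corepressor subunit, and Rprl1 with 61 each, Adgrl2 with 56, Trps1 with 55, Gm17746 with 54, Ext1 with 49, and Gm1653, Sgms1 and Xylt1 with 47 each. Over all 18998 genes with a peak the mean was 4.86 ± 5.34 (SD) and the median 3, and the 502 genes with 20 or more peaks held 14.6% of the peaks. Many of the leading genes have wide surroundings free of other TSSs in the annotation used: Adgrl2 had a territory of 1211 kb and Rprl1 1613 kb, but Sgms1, which makes sphingomyelin, only 232 kb. Rprl1 lies in the immunoglobulin kappa locus, and no peak there is given to any of its 168 gene segments. The territory of Rprl1 is therefore wide only because these segments do not count as genes with a TSS here.

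Peak density gave other genes. Mafg, a small Maf protein that pairs with NF-E2, had 5 peaks in a territory of 5.46 kb, or 91.5 peaks per 100 kb. Mir142, a microRNA gene of blood cells, had 6 peaks (61.9 per 100 kb), and the immediate early genes Zfp36 and Junb had 49.9 and 47.7 per 100 kb. Elof1 (60.3), Selenop (54.9), Wdr81 (54.5), Ctdsp1 (52.3) and Klf16 (48.6) were also among the 10 densest genes with at least 5 peaks. Hbb-b2, an adult beta globin name, stood at 71.4 peaks per 100 kb. That value is uncertain, since the list gives Hbb-b2 and Hbb-bt the same TSS on chromosome 7 and splits the peaks of the locus between the 2 names.

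The next comparison asked whether genes of each blood lineage have more peaks than other genes with as much room. B cell genes had 10.6 ± 10.9 peaks (SD, n = 19 genes), 2.21 times the 4.80 of matched random lists, and common lymphoid genes had 11.4 ± 10.4 (n = 16), 2.18 times. Stem and multipotent progenitor genes had 11.9 ± 10.6 (n = 20), 1.91 times, and megakaryocyte genes 8.59 ± 10.5 (n = 17), 1.90 times. Granulocyte and macrophage genes had 5.95 ± 4.96 (n = 20), 1.63 times, T cell genes 8.05 ± 7.86 (n = 20), 1.55 times, and erythroid genes 6.05 ± 6.41 (n = 20), 1.54 times the matched value. Housekeeping genes, which every cell uses, were also above matched lists at 5.28 ± 5.34 (n = 18), 1.61 times, and genes of unrelated tissues were below at 2.94 ± 1.85 (n = 17), 0.596 times. In all, 8 of the 14 lists were called above and 1 below. Permutation tests gave adjusted p = 0.0035 for the B cell and common lymphoid lists, 0.00485 for stem, 0.00735 for megakaryocyte, 0.0089 for granulocyte and macrophage and 0.0138 for housekeeping genes. For the erythroid and T cell lists (both 0.0492) and the unrelated tissues (0.049) the adjusted permutation p sat just under the threshold.

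**Figure D2:**
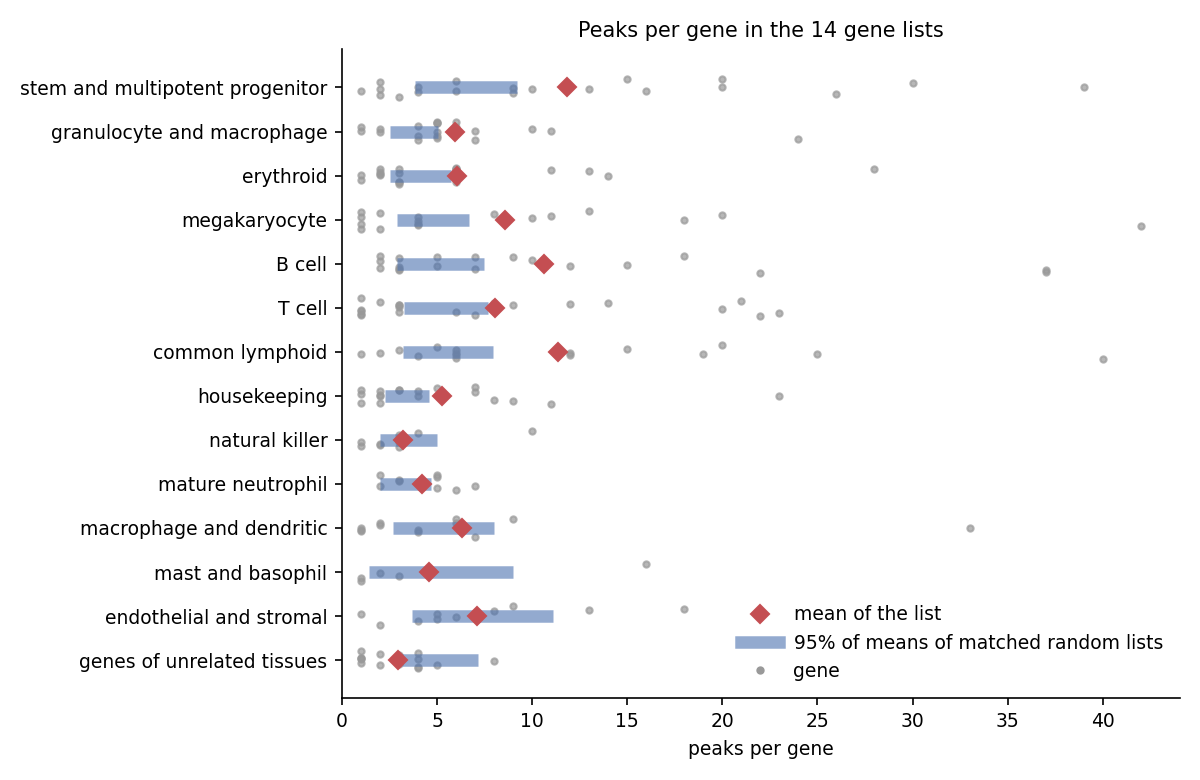
Number of peaks per gene for the members with a peak of the 14 lists (grey points), the mean of each list (red diamonds) and the range that holds 95% of the means of random lists matched on territory size (blue bars). The diamonds of the 7 blood lists and the housekeeping list lie to the right of their bars, and that of the unrelated tissues, at 2.94, lies to the left of its bar.

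In the B cell list, Foxo1 and Bach2, transcription factors of early and maturing B cells, had 37 peaks each, and Irf4, a regulator of light chain recombination and plasma cells, had 22. The peak nearest to the Foxo1 TSS lay in its promoter (chromosome 3, 52268000 to 52268498), and that of Irf4 likewise (chromosome 13, 30749019 to 30749517). The peak of Bach2 nearest to its TSS lay in intron 1 of 4 (chromosome 4, 32423620 to 32424118), 6.43 kb downstream. Another peak given to Bach2 (32238432 to 32238930) lay at the start of the gene, which the list does not take as its TSS, so Bach2 does not count below as a gene with a promoter peak. Vpreb1, a surrogate light chain gene, had no peak of its own, and the closest peak, 1.40 kb away, was given to Top3b. Above the median of genes of like territory were 16 of the 19 members with a peak.

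In the common lymphoid list, Bcl11a, a zinc finger factor that lymphoid development requires, had 40 peaks, Ets1 25 and Ikzf1, which encodes Ikaros, 20. Their nearest peaks lay at the promoters of Bcl11a (chromosome 11, 24077527 to 24078025) and Ets1 (chromosome 9, 32695803 to 32696301) and in the 5' UTR of Ikzf1 (chromosome 11, 11690033 to 11690531). Of the 16 members, 14 were above the median of genes of like territory, and the call ended with the median in place of the mean (1.79 times). In the T cell list, Themis, a signalling protein of thymocyte selection, had 23 peaks, the adhesion molecule gene Cd2 22 and Gata3, a factor of T cell commitment, 21. The promoters of Themis (chromosome 10, 28668189 to 28668687), Cd2 (chromosome 3, 101287882 to 101288380) and Gata3 (chromosome 2, 9878431 to 9878929) each held a peak. Only 11 of the 20 T cell genes were above the median of genes of like territory, and the call ended within 50 kb (1.37 times) and 10 kb (1.28 times) of a TSS, without territory matching (1.66 times), without Themis (1.47 times) and with the median (1.46 times). It also ended under the first territory map (1.55 times, adjusted permutation p = 0.061).

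In the stem and multipotent progenitor list, Runx1, a founding factor of blood stem cells, had 39 peaks, Erg 30 and Mecom, which encodes Evi1, 26. Their nearest peaks were at the promoters of Runx1 (chromosome 16, 92825750 to 92826248) and Erg (chromosome 16, 95459241 to 95459739) and in a 5' UTR of Mecom (chromosome 3, 30012807 to 30013305). Of the 20 members, 15 were above the median of genes of like territory. The granulocyte and macrophage list was led by Irf8, a factor of monocyte fate, with 24 peaks, Itgam, which encodes the surface marker CD11b, with 11, and Gfi1, a transcriptional repressor that neutrophil development requires, with 10. The promoters of Irf8 (chromosome 8, 120736201 to 120736699), Itgam (chromosome 7, 128062387 to 128062885) and Gfi1 (chromosome 5, 107725526 to 107726024) held a peak, and 14 of the 20 members were above the median of genes of like territory. The call for this list ended without territory matching (1.22 times) and under the first territory map (1.49 times, adjusted permutation p = 0.0586).

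In the erythroid list, Zfpm1, which encodes the GATA1 partner FOG1, had 28 peaks and Ank1, an ankyrin of the red cell membrane skeleton, 14. The peak nearest to the TSS lay at the promoter of Zfpm1 (chromosome 8, 122281505 to 122282003) and in exon 1 of 43 of Ank1 (chromosome 8, 23034989 to 23035487). The erythroid call ended without Zfpm1 (1.34 times), without territory matching (1.24 times) and with the median (1.28 times). The counts of the globin genes in the erythroid list are uncertain. Hbb-bt shares its TSS with Hbb-b2, which is in no list. The peak given to Hba-a1 lies closer to Hba-a2, and 1 of the 2 peaks given to Hba-a2 lies beside Hba-a1. What this does to the call was not tested. In the megakaryocyte list, Fli1, an ETS factor of megakaryocytes, had 42 peaks, the platelet integrin gene Itgb3 20 and the tetraspanin gene Cd9 18, with peaks at the promoters of Fli1 (chromosome 9, 32541218 to 32541716), Itgb3 (chromosome 11, 104607714 to 104608212) and Cd9 (chromosome 6, 125494430 to 125494928). Thbs1 had no peak of its own, but a peak 0.104 kb from the gene was given to Gm13986. The megakaryocyte call ended without Fli1 (1.53 times), without territory matching (1.76 times) and with the median (1.32 times), and only 9 of its 17 members with a peak were above the median of genes of like territory, against 14 of 20 in the erythroid list.

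**Figure D3:**
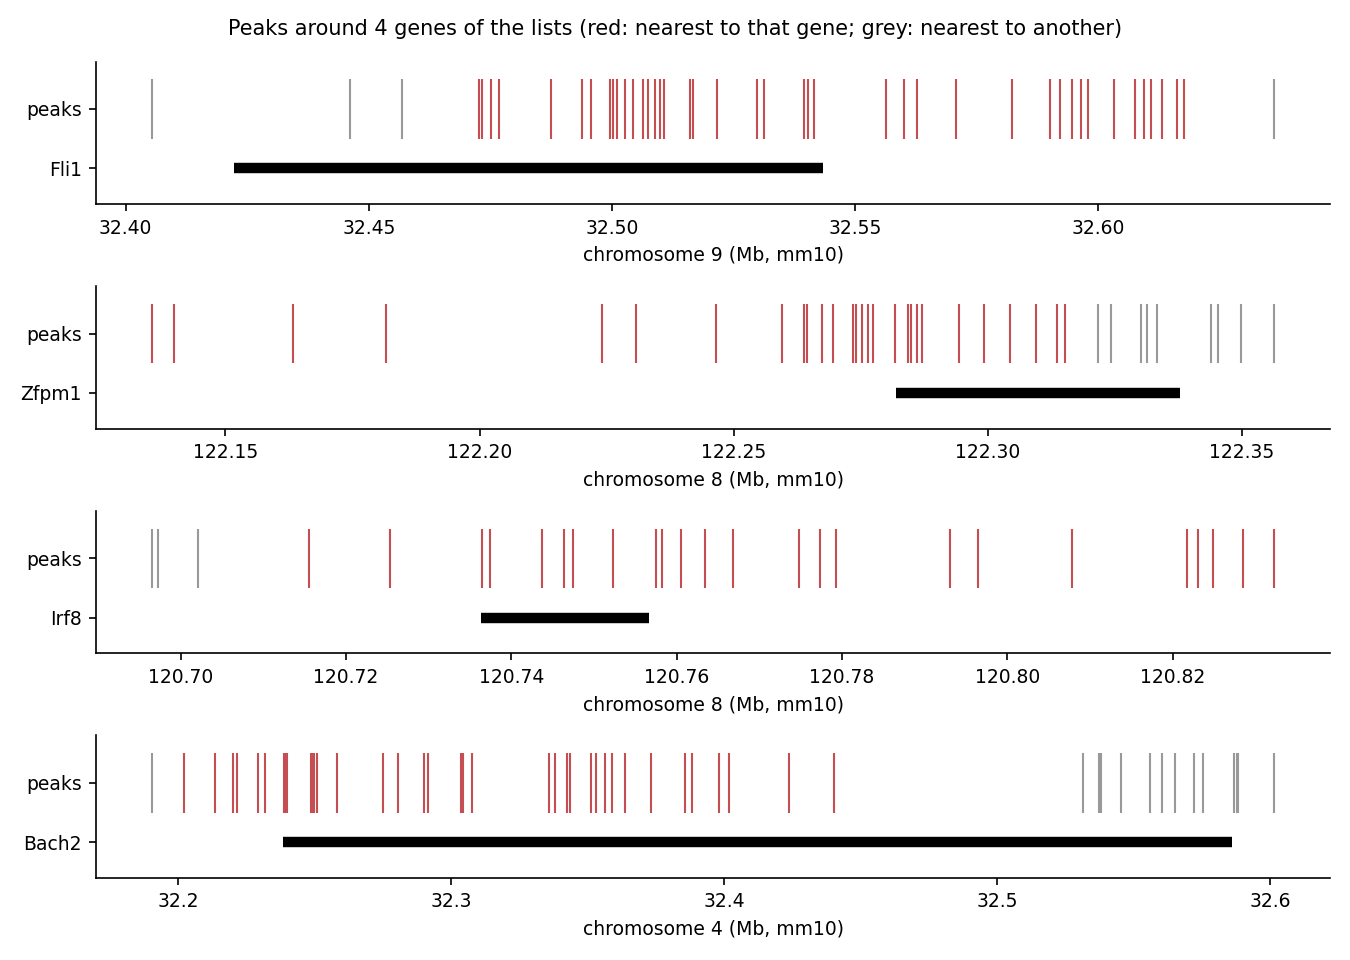
Position in Mb of the peaks around Fli1, Zfpm1, Irf8 and Bach2 on their chromosomes, with the gene as a black bar, peaks nearest to that gene in red and peaks nearest to another gene in grey. Fli1 had 42 peaks, Zfpm1 28, Irf8 24 and Bach2 37, in the genes and beyond a gene end, on both sides only for Irf8.

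Housekeeping genes were led by Ywhaz, a 14-3-3 protein gene, with 23 peaks, and Eef1a1 had 9. The housekeeping call ended within 10 kb of a TSS (1.39 times), without territory matching (1.08 times) and with the median (1.44 times). Among genes of unrelated tissues the numbers were low: the apolipoprotein gene Apoa1 had 8 peaks, Neurod1 5 and Ttr, Snap25 and Pax6 4 each, while Krt5, Sftpc and Umod had none. A peak 0.174 kb from Sftpc was given to Bmp1. The call of the unrelated tissues ended within 10 kb (0.711 times), without territory matching (0.605 times), with genes without a peak kept (0.688 times), with the median (0.898 times) and under the first territory map (0.621 times, adjusted permutation p = 0.0654).

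The 5 lists of other cell types, which a sort could have carried along, were not told apart from matched lists. Natural killer genes had 3.22 ± 2.73 peaks (SD, n = 9), 0.957 times the matched value, with Klrb1c at 10, Prf1 at 4, Eomes, Tbx21 and Gzmb at 3 and Ncr1 without a peak. Mature neutrophil genes had 4.20 ± 1.69 (n = 10), 1.31 times, led by S100a9 with 7, Cxcr2 with 6 and S100a8, Ly6g and Retnlg with 5. Macrophage and dendritic genes had 6.33 ± 8.80 (n = 12), 1.31 times, led by Tcf4, an E protein of plasmacytoid dendritic cells, with 33, Adgre1 with 9 and Siglech with 7. Mast and basophil genes had 4.6 ± 6.43 (n = 5), 1.21 times, with Mitf at 16, Cma1 at 3 and Cpa3 at 2, and Mcpt8, Fcer1a and Ms4a2 without a peak. Endothelial and stromal genes had 7.10 ± 5.17 (n = 10), 1.04 times, led by Kdr with 18, Cxcl12 with 13 and Cdh5 with 9. Adjusted permutation p ran from 0.268 to 0.963 in these lists, which are shorter than the blood lists. Whether the blood lists differ from them was not tested.

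Promoters separated the lists in another way. All 18 housekeeping genes and all 10 mature neutrophil genes, S100a8 and S100a9 among them, had a peak within 1 kb of a TSS. The same held for 15 of 16 common lymphoid genes (93.8%), 18 of 20 granulocyte and macrophage genes and 18 of 20 B cell genes (90.0% each), and 17 of 20 erythroid genes (85%), against 58.4% of all other coding genes with a territory. Of the unrelated tissues only 3 of 20 genes (15%, exact 95% interval 3.21 to 37.9) had one. Fisher's exact test gave adjusted p = 0.000752 for the housekeeping and unrelated lists, 0.0138 for the common lymphoid, granulocyte and B cell lists, 0.0162 for neutrophil and 0.0416 for erythroid genes. Not called were stem (70.0%), megakaryocyte (77.8%), T cell (75%), natural killer (80.0%), macrophage and dendritic (66.7%), endothelial (70.0%), and mast and basophil genes (25.0%). Within 500 bp the erythroid and B cell shares were 80.0% each and their calls ended.

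**Figure D4:**
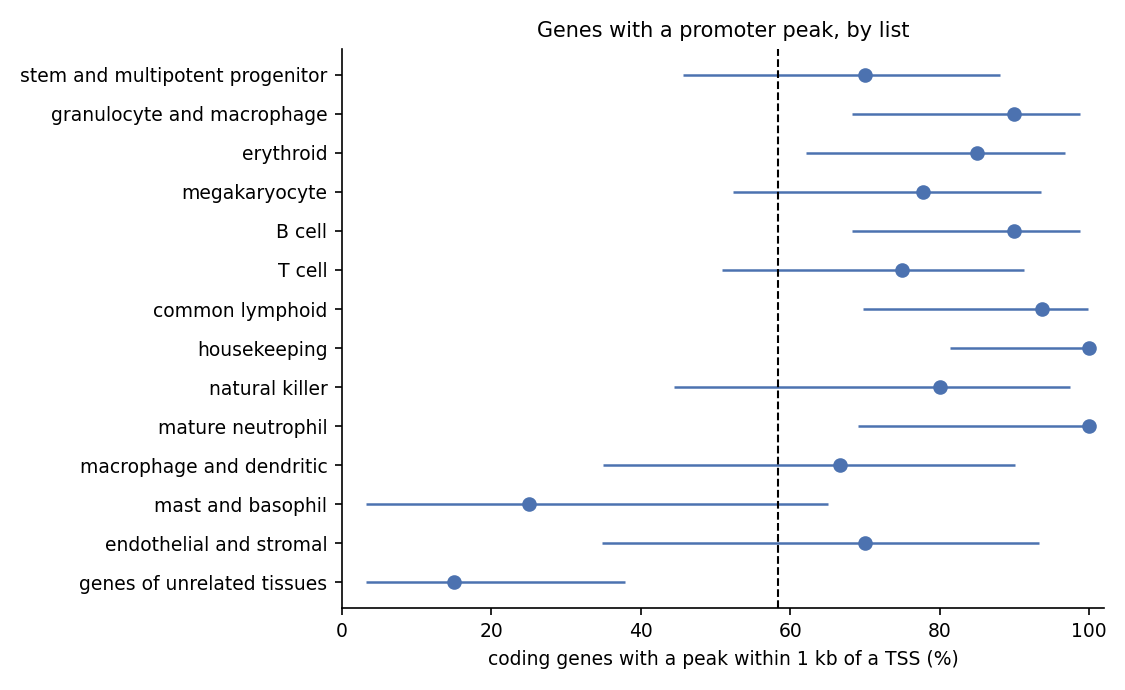
Share in percent of the coding genes of each list with a peak within 1 kb of a TSS, with exact 95% intervals as bars, and the share of all other coding genes with a territory as a dashed line at 58.4%. Housekeeping and mature neutrophil genes stand at 100%, and genes of unrelated tissues at 15%.

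Counted over peaks, stem and multipotent progenitor genes had a low share of promoter peaks: 23 of their 237 peaks (9.70%, exact 95% interval 6.25 to 14.2) lay within 1 kb of a TSS, against 16.2% of other peaks. Housekeeping genes had a high share, with 26 of 95 peaks (27.4%, 18.7 to 37.5). Fisher's exact test gave adjusted p = 0.0418 for both and called none of the other 12 lists. Peaks of 1 gene are not independent, and with genes in place of peaks as the unit neither call held (adjusted permutation p = 0.3 for both).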

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

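Neither item was part of a comparison above, and each stood out as a signal in data outside those comparisons. The families of the test on repeats were named before its result was seen, while their solo LTR names and the interval for chromosome Y were added only after the results were seen.

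Of the 92842 peaks, 6120 (6.59%, exact 95% interval 6.43 to 6.75) lay in LTR elements, the remains of endogenous retroviruses, more than in SINEs (3847) or LINEs (3051). The ERVL-MaLR family held 59.8% of them and ERVK 20.7%, and ORR1E (533 peaks), MTD (410) and ORR1D2 (301) were the leading elements. A technical explanation is that reads shared among recent near-identical copies were placed at random, which would put most of these peaks in the recent families. The families IAP, ETn, MMETn, MMERGLN, MMVL30 and MERVL held 1.70% of the LTR peaks, and 4.49% with the names of their solo LTRs added, which argues against that explanation for most of the peaks. No biological explanation was tested, and the share of LTR sequence in the genome was not used here, so whether 6.59% is high stays open.

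Chromosome Y held 14 peaks, of which 7 (50%, exact 95% interval 23 to 77) were nearest to the single-copy genes Kdm5d, Eif2s3y, Uty and Ddx3y, 6 to Erdr1 and 1 to Gm29089.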

How the results depend on the processing

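Over all alternatives 174 results counted as unchanged (8 annotation shares and 2 widths, which carry no call, among them), 31 lost a call and 1 gained one. The unchanged results also include lists without a shared gene, which leaving out shared genes could not alter. Lists without a call in either setting count as unchanged too, so the total does not measure how stable the calls are. No called result changed direction, but several ratios without a call crossed 1, such as mature neutrophil from 1.31 to 0.863 without territory matching. The B cell and stem lists kept their calls on peaks per gene under each alternative. Without territory matching the ratios that lost a call were granulocyte 1.22, erythroid 1.24, megakaryocyte 1.76, T cell 1.66, housekeeping 1.08 and unrelated tissues 0.605. Within 10 kb they were T cell 1.28, housekeeping 1.39 and unrelated 0.711, within 50 kb T cell 1.37, and with genes of 0 peaks kept unrelated 0.688. For the promoter share of peaks, the odds ratios of stem and housekeeping genes were 0.516 and 1.47 within 500 bp and 0.613 and 1.69 without peaks over 100 kb, all without a call, while the erythroid list was called at 1.87 within 2 kb. The next 4 alternatives were chosen only after the results were seen. The first territory map gave granulocyte 1.49, T cell 1.55 and unrelated 0.621, so these 3 calls rest on the revised map. Without the richest member the values were erythroid 1.34, megakaryocyte 1.53 and T cell 1.47. Medians gave erythroid 1.28, megakaryocyte 1.32, T cell 1.46, common lymphoid 1.79, housekeeping 1.44 and unrelated 0.898. With genes as the unit the promoter odds ratios of stem and housekeeping genes were 0.555 and 1.95, without a call. The promoter share of genes and its alternatives were also added at that point, and within 500 bp the erythroid and B cell shares lost their calls at 80.0% each. The cause was not tested in any case. Annotation shares in a random subset of the peaks stayed within the exact intervals of the full list for all 8 classes. A random subset of the same peaks must lie close to the full list, so this says nothing about the processing. No paired analysis was possible because no values per library were analysed, and for the same reason the alternatives planned for the 9 comparisons, for gene list shifts and for accessibility by cell type were not run. Those for motifs were not run for want of a sequence, nor was the split by peak width, since all peaks have the same width. Depth is unknown, so what it limits cannot be stated.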

Other observations

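The tests on the pooled blood genes, with the comparison with housekeeping genes, were chosen only after peak counts of the lists had been seen, as were the antigen receptor loci, the densest windows, the name patterns of the families in their present form, and the enhancer count with 5' gene ends. The TSS positions behind the enhancer count were revised along with the territory map.

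Gene families picked by name, apart from the lists, differed widely. Some of their members are also in the lists, such as Irf4 and Irf8, so these ratios are not independent of the list tests. Olfactory receptor genes, used in the nose, had 0.217 ± 0.744 peaks per gene (SD, n = 1107), 0.114 times the mean of random genes of like territory, and vomeronasal receptor genes 0.172 ± 0.621 (n = 355), 0.0483 times. Keratin (0.464 times), protocadherin (0.477 times), Hox (0.532 times) and microRNA genes (0.869 times) also lay below. Interferon regulatory factor and Stat genes, which carry cytokine signals in immune cells, stood highest at 8.38 ± 7.79 peaks (n = 16), 2.41 times, followed by integrin (1.85 times), CD surface antigen (1.68 times), chemokine (1.53 times), histone (1.42 times) and solute carrier genes (1.17 times). These 12 of 17 families passed permutation tests with 20000 draws, with adjusted p from 0.00034 to 0.0132. Zfp (0.931 times), ribosomal protein (1.15 times), interleukin (1.23 times), proteasome (1.09 times) and potassium channel genes (0.933 times) did not, with adjusted permutation p from 0.107 to 0.6. In the first patterns, which took in genes with like names such as Irf2bp2, the interferon regulatory factor and Stat ratio was 2.96 and the same families passed. Members of some families, such as the clustered histone and Hox genes, lie side by side, while the random genes were drawn singly. Counts of such neighbours are not independent, so the p-values of these families may be too small.

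The loci that V, D and J segments assemble from were open in places, but their peaks carry other gene names. The immunoglobulin kappa locus (chromosome 6, 67555636 to 70726754) held 120 peaks, or 37.8 per Mb, of which 61 were given to Rprl1, 36 to 4930515G16Rik and 23 to Rpia. All peaks given to Rprl1, which shares the third place among all genes by peak number, lay in that locus. The heavy chain locus on chromosome 12 held 109 peaks (39.6 per Mb), the T cell receptor beta locus on chromosome 6 held 45 (67.5 per Mb) and the alpha locus on chromosome 14 held 41 (22.8 per Mb), 29 of them given to Dad1. The short lambda, gamma and delta loci held 10, 11 and 9 peaks (50.2, 63.1 and 33.6 per Mb). The delta locus lies within the alpha locus, so its peaks are also counted among those of the alpha locus. The autosomes held 37.6 peaks per Mb on average, so the kappa and heavy chain loci lay near that mean. The alpha locus lay below its own chromosome, which held 28.2 per Mb. The densest windows of 100 kb held 31 peaks each and were found at Gpr183 (chromosome 14), Pip4k2a (chromosome 2) and Gse1 (chromosome 8). Around Zfpm1 such a window held 30 peaks and around Fli1 29, while the 99th percentile over all peaks was 22 and the median 8.

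Taken as 1 group, the 128 genes of the 7 blood lists with a peak had 8.93 peaks on average, 1.87 times the 4.79 of random genes matched on territory size (permutation p = 2e-05, the smallest that 100000 draws can give), which argues against territory size as the cause. Without the 10 genes with the most peaks the ratio was 1.58, and among the 86 genes that are no transcriptional regulators it was 1.51 against genes of that kind, which argues against a few rich members and against regulators in general. Members were classed by their gene descriptions, with Spi1, Nfe2, Tal1, Ebf1, Mecom, Hlf and Notch1 added by hand after the result was seen, and the 42 regulators lay at 1.98 times. It stays open whether genes in use in any cell type have more peaks: over the mean of genes of like territory, blood genes stood at 1.66 ± 0.900 (SD, n = 128) and housekeeping genes at 1.45 ± 0.800 (n = 18), a difference of 0.212 with permutation p = 0.344. The excess may therefore belong to active genes rather than to blood genes, and the list gives no levels of expression to tell these apart. Families that share members with the housekeeping list did not pass, with ribosomal protein genes at 1.15 times and proteasome genes at 1.09 times. With genes without a peak kept, as for those families, the housekeeping list stood at 2.10 times, so these sets differ and the question stays open.

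Of 22 enhancers of blood genes, written down by their distance to the TSS from memory, without a source being consulted, before their peaks were examined, 17 had a peak centre within 1 kb. Shuffling the distances among the genes gave 6.73 on average and at most 15 (one-sided permutation p = 1e-05, the smallest that 100000 draws can give), and distances mirrored to the other side of the TSS gave 3, which argues against local peak density as the cause. The enhancers with a peak included those 14 kb upstream of Spi1 (chromosome 2, 91082890 to 91083388), 37 kb downstream of Cebpa (chromosome 7, 35155859 to 35156357), 56 kb downstream of Irf8 (chromosome 8, 120792767 to 120793265) and 77 kb upstream of Gata2 (chromosome 6, 88120739 to 88121237), all intergenic, and the peaks of Spi1, Cebpa and Gata2 carry the names Slc39a13, Slc7a10 and Mir6376. Without a peak within 1 kb, counted from the TSS used here, were Gata2 -2.8 and +9.5 kb, Runx1 +23 kb, Erg +85 kb and Rag2 -22 kb. Adding the 5' gene end as an origin gave 18 of 22. The gain was Gata2 +9.5 kb, which from that end falls within a listed peak (chromosome 6, 88203085 to 88203583). For the others, other promoters used as the origin may still play a part. The TSS positions of the first territory map gave 17 with permutation p = 7e-05. That blood enhancers of several lineages are in the list stays a hypothesis for the list as a whole, since which cell types had each peak was not analysed here.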
